A study of Homo sapiens with 6 samples.

How the data were processed

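RNA from SK-N-SH neuroblastoma cells was measured in 6 samples, 3 cultured with medium alone and 3 with dopamine for 6 h. Per the labels' protocols, RNA was extracted with TRIzol, cytoplasmic and mitochondrial ribosomal RNA was removed, and stranded libraries of total RNA were made with random primers. Groups and replicate numbers came from the sample titles. Such libraries hold transcripts with and without poly(A) tails, so unspliced and nuclear RNA adds to the values.

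The authors deposited 1 table of FPKM values for 26789 genes with gene identifiers, symbols, types and hg19 coordinates. Per the submitters' processing notes, FastQC 0.11.9, STAR 2.7.1a, HTSeq 0.11.2, DESeq2 1.40.2 and the hg19 build were used, with no role given for any. How FPKM was made from the counts, the gene annotation and the strand setting of the counting are not given in the sources used here, so values of genes that overlap on either strand, or that have near-identical copies, are uncertain. Every gene in the table had a value above 0 in at least 1 sample, and genes on 24 chromosomes were listed. FPKM divides by the total of each library, so a rise of a few abundant genes lowers all others, and FPKM values cannot be tested with count models.

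The table gives no totals. Depth was recovered from 2795 pseudogenes with a genomic span between 150 and 1500 bases. They were taken to have a single exon, which was not checked, so that their FPKM moves in steps of 1 fragment. Only low values were tested, 1171 to 1322 in each library. With the recovered totals, 92.5 to 94.1% of the tested values were whole numbers of fragments within 0.03. The totals ran from 19433000 to 24225000 fragments, a ratio of 1.25, and on simulated data with 3 known depths the largest error was 0.146%. Which reads the authors' total included is not given in the sources used here.

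Values were analysed as log2(FPKM + 0.5), so fold changes of low genes are understated. Genes with a mean FPKM of 1 or more over all 6 samples were kept, which left 11791 genes, 10267 of them protein-coding. The median within-group SD was 0.14 log2 units. Groups were compared with limma 3.58.1 in R 4.3.3 (moderated test with an intensity trend in the prior variance, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), with no block for the replicate number. Gene lists were written from textbook knowledge before the data were examined, as were the test, the alternative settings and the rule for named genes. Of 32 lists, 24 had at least 5 measured members and were tested with camera at a preset correlation of 0.01. Alternatives used camera with an estimated correlation, and fry, which asks whether the genes of a list move one way on balance. Of the 4 lists past the threshold none held with an estimated correlation, and 1, the unfolded protein response, did so after the GC and length correction. With fry 3 of the 4 held, the G2/M list did not, and the ATF4 list passed as well. Members were counted over all genes and adjusted over the list alone.

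Named genes were the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, leaving out clone names and small RNAs, up to 4 members with the smallest p of each list that passed and of 8 lists always described, and TGM2, DRD2, MKI67, CCND1, CDKN1A, MYCN, TH and HMOX1 whatever their result. Genes from the same lists were added to describe a group. Genes outside this rule were chosen after their values were seen: the genes called only after the GC and length correction and those of the cytoskeleton.

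Alternatives chosen beforehand were pseudocounts of 0.1 and 1, filters at mean FPKM 0.3 and 5 and none, median-of-ratios, TPM and quantile scaling, no trend, a robust prior, sample quality weights, a replicate block, a threshold of 0.01 and leaving out each library. The median log2 fold change of all genes was 0.08 as deposited, 0.00 after median-of-ratios scaling, -0.01 after quantile normalization and 0.10 after TPM scaling. After seeing the data a correction was added, a loess fit (span 0.5) of each library's deviation from the gene means on GC content and log2 length of the longest transcript. GC content and length came from the GRCh38 annotation by gene identifier, with no coordinates taken from it, and 98.2% of the tested genes (11579) had both. Since the trend differed between the groups, this correction can remove part of a real difference.

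On simulated values for 11579 genes of the comparison, the test recovered 73.1% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold. The changed genes were drawn from those with a mean log2 value above 2. A GC trend was then added with the observed slopes, but with those of control replicate 2 and dopamine replicate 2 exchanged. With it the test recovered 34.3%, 91% and 100%, and after the correction 71.6%, 98.5% and 100%. The simulated slopes of the 2 groups overlapped, whereas the observed ones did not. These shares therefore do not cover a trend that separates the groups. The simulated spread was drawn from the fit to the uncorrected values, so it already held the trend differences within the groups. The added trend was linear in the GC content that the correction fits, so its removal was built in. The recovery after the correction thus does not tell how well the correction works on the measured values. Figures were drawn with matplotlib 3.10.9.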

Results

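RNA was measured in SK-N-SH cells, a human neuroblastoma line, after 6 h in medium alone (control, n = 3) or in medium with dopamine (n = 3). The labels print the dopamine dose as 40 M, a unit that seems to have lost its prefix, so the dose is not interpreted here. The series design text names SH-SY5Y as the treated line, whereas all 6 samples are labelled SK-N-SH. SH-SY5Y is a subline of SK-N-SH. The labels number the replicates 1 to 3 in each group and do not say that they came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Ribosomal RNA was removed and the libraries kept strand information. Values were FPKM (fragments of a gene scaled to its length and to the library's total) for 26789 genes. Depth, recovered from the steps between the low values of short pseudogenes, was about 22692000, 24225000 and 20630000 fragments in control replicates 1, 2 and 3, and 20706000, 19433000 and 21352000 in dopamine replicates 1, 2 and 3. At this depth 1 FPKM in a gene of 1 kb stood for 19.4 to 24.2 fragments. The correlation of log2 values between any pair of libraries lay between 0.957 and 0.994.

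The comparison of dopamine with control cells addressed the study's question of how dopamine acts on the growth of these cells. HMOX1, which encodes the heme-degrading enzyme heme oxygenase 1, had the largest rise, from 33 ± 4.74 FPKM in control cells to 429 ± 39.5 FPKM with dopamine (SD, n = 3 per group), 12.9-fold on the log2(FPKM + 0.5) scale. Genes of the endoplasmic reticulum chaperone system rose with it, among them HERPUD1 (2.13-fold), the chaperone gene HSPA5 (1.94-fold) and MANF (1.59-fold), as did the antioxidant genes GCLM (2.38-fold) and TXNRD1 (1.98-fold). MAT2A, which encodes the enzyme that makes S-adenosylmethionine, rose 2.17-fold. NTSR1, the neurotensin receptor gene, fell by 1.0 on the log2 scale, from 18.1 ± 2.05 to 8.83 ± 1.10 FPKM. No member of the lists for cell division, the p53 response or apoptosis passed the adjusted threshold. At an unadjusted p under 0.05 (limma) lay 23 of 38 G2/M, 14 of 36 G1/S, 20 of 28 p53 and 14 of 23 apoptosis genes. Over all tested genes it was 3829 of 11791. After a correction for GC content and transcript length these counts were 6, 11, 8 and 5, and 1964 of 11579 over all genes. The G2/M list passed camera narrowly (adjusted p = 0.0494) and failed after the correction (camera adjusted p = 0.0975).

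In total 12 of 11791 tested genes passed an adjusted p of 0.05 (limma with an intensity trend, two-sided, Benjamini-Hochberg), 10 of them higher and 2 lower with dopamine, and 5 changed at least 2-fold (23 without control replicate 1, 3 without control replicate 2, and HMOX1 alone after a correction for GC content and transcript length). Without an adjustment, 3829 genes had a p under 0.05, 2880 higher and 949 lower, where 590 are expected by chance. That number was 2268 without control replicate 2, 1937 without control replicate 3, 1992 without dopamine replicate 3, 1541 without both replicates numbered 3 and 1964 after the GC and length correction. In 4531 genes (38.4%) the 3 dopamine values all lay on one side of the 3 control values, against 10% by chance. The count of 12 depended on single libraries: it was 2177 without control replicate 1, 3 without control replicate 2, 6 without control replicate 3, 6 without dopamine replicate 1 and 7 without dopamine replicate 3. It was 2706 with sample quality weights, 27 after quantile normalization, 6 with no filter on low values, 5 with no trend in the prior variance and 28 after a correction for GC content and transcript length chosen after seeing the data. Of the calls, 10 of 12 were rises, and after quantile normalization 66.7% were.

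HMOX1 (ENSG00000100292.12, hg19 chromosome 22, 35776354 to 35790207) had a log2 fold change of 3.69 (SE 0.11, adjusted p = 6.06e-07). Its control values were 32.0, 38.2 and 28.9 FPKM and its dopamine values 426, 470 and 392 FPKM. It passed the threshold in all 22 alternative settings, with a log2 fold change between 3.60 and 3.79. MAT2A (ENSG00000168906.8, chromosome 2, 85766288 to 85772403) went from 53.9 ± 2.59 to 118 ± 4.68 FPKM (adjusted p = 0.00035) and HERPUD1 (ENSG00000051108.10, chromosome 16, 56965960 to 56977798) from 10.6 ± 1.06 to 23.1 ± 0.798 FPKM (adjusted p = 0.0024), and both also passed in all 22 settings. The other 9 called genes kept their direction in 22 of 22 settings and passed the threshold in 9 to 18 of them.

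**Figure D1:**
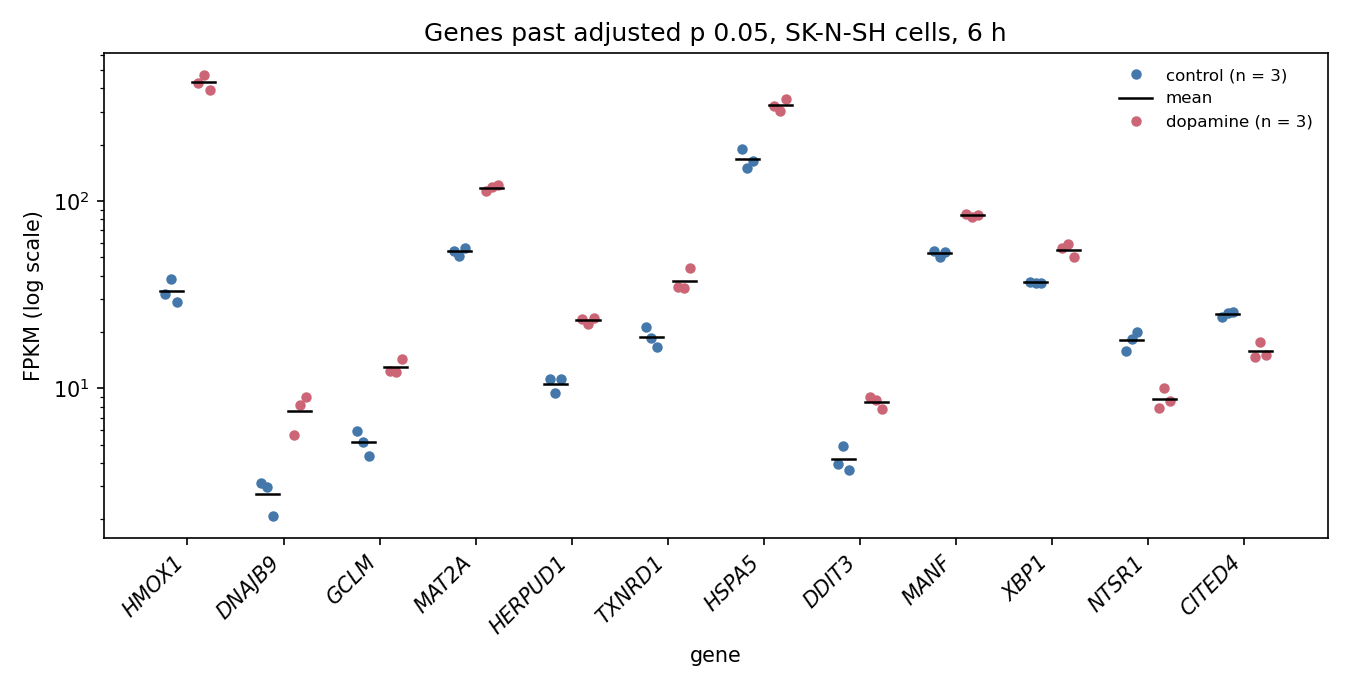
FPKM on a log axis of the 12 genes past an adjusted p of 0.05 (horizontal axis) in SK-N-SH cells after 6 h. Points are the 3 control (blue) and 3 dopamine (red) libraries and black lines are group means, and HMOX1 stands at 33 FPKM in control cells and 429 FPKM with dopamine.

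The fixed list of the endoplasmic reticulum unfolded protein response had 22 measured members. Of these 5 rose and 17 did not pass, 20 rose when adjusted over the list alone, and all 22 had a higher mean with dopamine, also after median-of-ratios, TPM and quantile scaling. The median log2 fold change was 0.55. HSPA5 (ENSG00000044574.7, chromosome 9, 127997132 to 128003609) went from 168 ± 19.7 to 325 ± 24.2 FPKM, a log2 fold change of 0.96 (SE 0.10, adjusted p = 0.0079). MANF, which encodes a secreted factor induced by misfolded protein, went from 52.5 ± 2.11 to 84.0 ± 1.87 FPKM (adjusted p = 0.0079). DNAJB9, a cochaperone gene, went from 2.73 ± 0.557 to 7.59 ± 1.77 FPKM (2.49-fold, adjusted p = 0.0487). The transcription factor gene XBP1 went from 36.9 ± 0.284 to 55.0 ± 4.21 FPKM (1.48-fold, adjusted p = 0.0436). The list passed the camera test with a preset correlation (adjusted p = 1.37e-12) and missed the threshold with an estimated one (adjusted p = 0.152 with an estimated correlation). After the GC and length correction 10 members rose, the median was 0.34, and the list also passed with an estimated correlation (adjusted p = 0.021). XBP1 then had a log2 fold change of 0.25 (SE 0.12, adjusted p = 0.324) against 0.57 (SE 0.08) before.

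The list of NRF2 target genes, which answer oxidative stress, had 26 measured members, of which 3 rose, 23 did not pass, and 14 rose when adjusted over the list alone. The median log2 fold change was 0.32. GCLM (ENSG00000023909.5, chromosome 1, 94350761 to 94374966), a subunit gene of the enzyme that limits glutathione synthesis, went from 5.17 ± 0.786 to 13 ± 1.24 FPKM (adjusted p = 0.00626). TXNRD1 (ENSG00000198431.11, chromosome 12, 104609557 to 104744061), which encodes thioredoxin reductase, went from 18.8 ± 2.31 to 37.7 ± 5.31 FPKM (adjusted p = 0.0199). The cystine transporter gene SLC7A11 stood at 1.13 ± 0.302 and 3.36 ± 0.753 FPKM and did not pass (adjusted p = 0.0753). NQO1, a member also known as an NRF2 target in many cells, stood at 84.4 ± 6.35 and 108 ± 6.18 FPKM (adjusted p = 0.11). The list passed camera with a preset correlation (adjusted p = 5.32e-05, and 0.000677 without HMOX1) and did not with an estimated one (adjusted p = 0.152, and 0.19 without HMOX1, with an estimated correlation). After the GC and length correction 5 members rose and the median was lower, at 0.17, with an adjusted p of 9.86e-11, or 0.23 with an estimated correlation.

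Among 12 measured genes of iron regulation HMOX1 alone rose, and 6 rose when adjusted over the list alone. The median log2 fold change was 0.38 and 11 members had a higher mean with dopamine, 10 after median-of-ratios scaling. The zinc and iron transporter gene SLC39A14 stood at 14.5 ± 1.59 and 19.3 ± 1.01 FPKM, the ferritin receptor gene NCOA4 at 20.5 ± 3.23 and 30.2 ± 4.41 FPKM, and FBXL5, an iron-sensing ubiquitin ligase subunit gene, at 6.51 ± 0.540 and 9.51 ± 1.02 FPKM. None of these 3 passed (adjusted p = 0.11 for each). The list passed camera (adjusted p = 0.00213, and 0.0475 without HMOX1) and did not with an estimated correlation (adjusted p = 0.535 with an estimated correlation). After the GC and length correction, which covered 11 of the 12 genes and not NCOA4, its median was 0.11 (camera adjusted p = 0.00206, or 0.23 with an estimated correlation). The corrected list still held HMOX1 (corrected log2 fold change 3.77), so its pass may rest on that gene. HMOX1 belongs to both this list and the NRF2 list.

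The ATF4 list, of amino acid supply and the integrated stress response, had 29 measured members. DDIT3 (ENSG00000175197.6, chromosome 12, 57910371 to 57914300), which encodes the stress transcription factor CHOP, rose from 4.19 ± 0.636 to 8.48 ± 0.647 FPKM (1.92-fold, adjusted p = 0.028). The other 28 did not pass, among them ATF4 itself at 43.3 ± 1.23 and 47.5 ± 1.93 FPKM (adjusted p = 0.215) and ASNS, an asparagine synthetase gene, at 5.02 ± 0.548 and 6.91 ± 0.392 FPKM (adjusted p = 0.11). Adjusted over the list alone, 8 rose and 1 fell. The list did not pass camera (median log2 fold change 0.13, adjusted p = 0.397), but did pass fry (adjusted p = 0.0117) and camera after the GC and length correction (adjusted p = 3.11e-05, or 0.23 with an estimated correlation). Of 20 heat shock genes none passed in limma, 8 had an unadjusted p under 0.05 (camera adjusted p = 0.716), and HSPA1A stood at 20.6 ± 1.43 and 20.2 ± 0.249 FPKM.

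**Figure D2:**
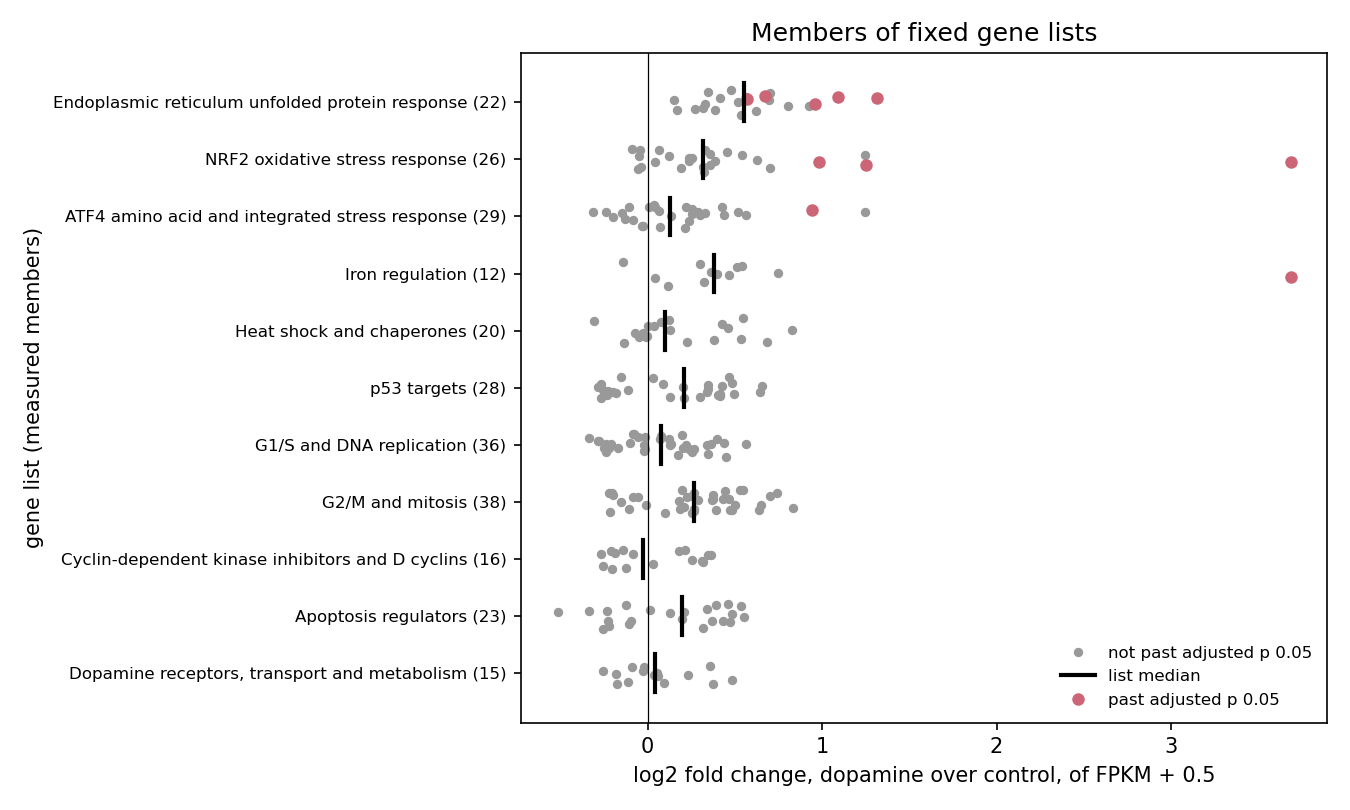
Log2 fold change of FPKM + 0.5, dopamine over control (horizontal axis), of the measured members of 11 gene lists (vertical axis, number of measured members in brackets). Each point is a gene, red where its adjusted p was under 0.05, and black bars are list medians, which reach 0.55 in the unfolded protein response list and 0.32 in the NRF2 list.

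Genes of cell division were examined because the study concerns growth. None of 36 measured genes of the G1/S transition and DNA replication passed in limma, nor when adjusted over the list alone, while 7 were higher and 7 lower at an unadjusted p under 0.05. Their median log2 fold change was 0.07 against 0.08 over all tested genes and -0.01 after median-of-ratios scaling (camera adjusted p = 0.824). CDC6, a replication licensing gene, stood at 8.78 ± 0.860 and 12.1 ± 1.11 FPKM, whereas MCM2, a subunit gene of the replicative helicase, stood at 29.5 ± 1.71 and 24.3 ± 1.83 FPKM (adjusted p = 0.11 for both). Of 38 measured genes of G2/M and mitosis none passed over all genes, 20 were higher and 3 lower at an unadjusted p under 0.05 (6 members in all after the GC and length correction), 11 rose when adjusted over the list alone, and the median was 0.27. TOP2A, a topoisomerase gene of dividing cells, stood at 5.69 ± 1.87 and 10.2 ± 1.75 FPKM and the mitotic kinase gene AURKA at 13 ± 0.539 and 16 ± 1.03 FPKM (adjusted p = 0.11 for both). MKI67, a proliferation marker, stood at 6.84 ± 1.66 and 8.03 ± 1.49 FPKM (adjusted p = 0.361), with a mean below control when control replicate 3 and dopamine replicate 3 were left out. The G2/M list passed camera narrowly (adjusted p = 0.0494), failed with an estimated correlation (adjusted p = 0.977 with an estimated correlation) and with fry (adjusted p = 0.202), and failed after the GC and length correction (median 0.07, adjusted p = 0.0975). It also failed without control replicate 1 (adjusted p = 0.0644), without dopamine replicate 2 (0.0858) and without dopamine replicate 3 (0.0861), and in 13 of 20 alternative settings in all.

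Among 16 cyclin-dependent kinase inhibitor and D cyclin genes and their partners none passed over all genes or when adjusted over the list alone, and 5 had an unadjusted p under 0.05 (camera adjusted p = 0.438). CDKN1A, which encodes the inhibitor p21, stood at 231 ± 8.83 and 192 ± 11.8 FPKM, a log2 fold change of -0.27 (SE 0.08, adjusted p = 0.11), and CCND1, the cyclin D1 gene, at 85.3 ± 3.93 and 73.6 ± 5.18 FPKM (adjusted p = 0.122). Of 28 p53 target genes none passed and 20 had an unadjusted p under 0.05 (camera adjusted p = 0.87), while 6 rose and 1 fell when adjusted over the list alone, with PLK2 at 12.2 ± 1.39 and 17.4 ± 1.99 FPKM and CDKN1A as the member that fell. After the GC and length correction 8 p53 targets had an unadjusted p under 0.05, and the list's median log2 fold change was 0.03 against 0.21 before. Of 23 apoptosis regulators none passed and 14 had an unadjusted p under 0.05 (camera adjusted p = 0.936), and 9 rose and 4 fell when adjusted over the list alone. After the correction 5 had an unadjusted p under 0.05 and the median was 0.09 against 0.20 before. CASP8 stood at 2.72 ± 0.109 and 3.72 ± 0.228 FPKM and BCL2L1 at 51.8 ± 4.46 and 41.0 ± 4.21 FPKM (adjusted p = 0.11 for both).

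The dopamine list of receptors, transport and metabolism had 15 measured members, none of which passed over all genes or when adjusted over the list alone, and 3 of which had an unadjusted p under 0.05 (camera adjusted p = 0.87). TGM2, a transglutaminase gene whose enzyme can attach dopamine to proteins, was abundant at 661 ± 37.9 FPKM in control and 587 ± 83.4 FPKM in dopamine cells (log2 fold change -0.18, SE 0.11, adjusted p = 0.275). The D2 receptor gene DRD2 was low, at 1.18 ± 0.111 and 1.23 ± 0.121 FPKM (log2 fold change 0.04, adjusted p = 0.855), and its sign turned after median-of-ratios (-0.03) and quantile (-0.10) scaling and without control replicate 1 or dopamine replicate 1 (-0.02 for each). DBH, which encodes the enzyme that turns dopamine into noradrenaline, stood at 24.1 ± 1.43 and 20.2 ± 3.42 FPKM, and MAOA, which encodes a dopamine-degrading oxidase, at 4.04 ± 0.504 and 5.33 ± 0.779 FPKM (adjusted p = 0.161 and 0.122). Of the histone H4 genes, whose transcripts mostly lack poly(A) tails and whose near-identical copies can share reads, 3 were measured and none passed, 1 of them (HIST1H4K) having an unadjusted p under 0.05. HIST1H4H stood at 3.39 ± 0.706 and 4.2 ± 0.326 FPKM and HIST1H4K at 3.27 ± 0.510 and 2.09 ± 0.917 FPKM. MYCN lay below the filter at 0.120 ± 0.117 and 0.167 ± 0.0673 FPKM, and TH was not analysed here.

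Both falling genes lay outside these lists. NTSR1 (ENSG00000101188.4, chromosome 20, 61340189 to 61394123) had a log2 fold change of -1.0 (SE 0.12, adjusted p = 0.0156). CITED4 (ENSG00000179862.5, chromosome 1, 41326729 to 41328018), which encodes a transcriptional cofactor, went from 24.9 ± 0.732 to 15.8 ± 1.68 FPKM, a log2 fold change of -0.64 (SE 0.09, adjusted p = 0.0487), and of -0.38 (SE 0.09, adjusted p = 0.138) after the GC and length correction.

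The libraries also differed in how expression depended on GC content, and this moved with the groups above. The slope of each library's deviation per 10 points of GC content was 0.02, 0.11 and 0.22 log2 units in control replicates 1, 2 and 3 (mean 0.116 ± 0.0986) and -0.03, -0.06 and -0.26 in dopamine replicates 1, 2 and 3 (mean -0.116 ± 0.122; exact permutation test, two-sided, p = 0.1, the smallest p that 3 against 3 allows). The first principal component held 66.4% of the variance, with control replicate 3 and dopamine replicate 3 at its ends, and 38.1% after the GC and length correction. The 5 measured members of the nuclear-retained RNA list, a sign of library or RNA quality, all had a higher mean with dopamine. Their median log2 fold change was 0.48 (camera adjusted p = 0.0796, or 0.977 with an estimated correlation) and 0.16 after the GC and length correction. In limma 4 of them had an unadjusted p under 0.05 before the correction and 1 after it. The 4 measured epithelial markers all had a lower mean with dopamine before the correction (median -0.32), and all 4 stayed lower after it (median -0.22). Before the correction 2 of them, KRT18 and KRT8, fell when adjusted over the list alone. In limma 2 had an unadjusted p under 0.05 before the correction and 2 after it.

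**Figure D3:**
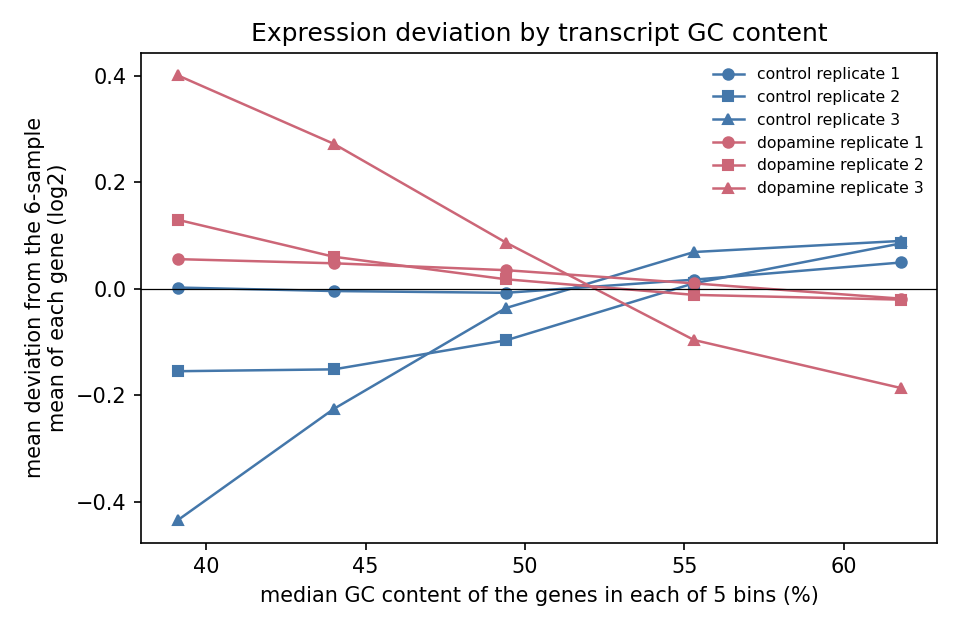
Mean deviation of each library from the 6-sample mean of each gene, in log2 units (vertical axis), over genes in 5 equal bins of transcript GC content (horizontal axis, median percent of each bin). Lines are the 3 control (blue) and 3 dopamine (red) libraries, and in the bin with the lowest GC content control replicate 3 lies at -0.43 and dopamine replicate 3 at 0.40.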

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

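The GC and length correction, its combinations, the protein-coding subset and the removal of both end libraries were chosen after seeing the data, and the other alternatives before. The 12 calls became 6 with no filter, 27 with quantile normalization, 5 with no trend, 2706 with sample quality weights, 7 without both libraries at the ends of the first component, 28 with the GC and length correction and 6 at a threshold of 0.01. Leaving out 1 library at a time gave 3 to 2177 calls. The 5 changes of at least 2-fold became 3 with no filter, 9 with sample quality weights and 1 with the GC and length correction (also 1 with its block), and 3 to 23 without 1 library. The 28 calls after the correction became 9 to 13 without 1 library. Of 4 lists, 0 passed with an estimated correlation, 1 with that and the GC and length correction, and 3 with fry, which lost the G2/M list and added the ATF4 list. DRD2 reversed to -0.0253 with median-of-ratios and -0.0976 with quantile scaling and ranged from -0.0173 to 0.0745 without 1 library, and MKI67 reversed to -0.03 without both end libraries. Whether the replicate numbers pair the samples stays open. Deviations of same-numbered libraries correlated at -0.2, 0.28 and -0.37, and 1 of 3 numbers matched its own partner best. After the GC and length correction these correlations were 0.15, 0.31 and 0.026. With a replicate block 3 genes passed, all 3 changed at least 2-fold, and 8 passed with the block after the correction. Where no cause is given, the cause was not tested. Of 997 comparisons of 46 named genes with an alternative, 872 kept direction and side of the threshold, 74 lost it, 46 gained it and 5 turned sign. Depth limits genes near 1 FPKM, where 1 kb holds as few as 19.4 fragments.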

Other observations

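Tests of the correction for GC content, of the splits of the samples, of each list across splits, of the NRF2 list without HMOX1 at an estimated correlation, of the cytoskeletal list and of its 2 parts were chosen after the results that led to them were seen. Of the 28 genes past the threshold after the correction for GC content and transcript length, 10 were among the 12 called without it and 18 were not. Of those 18, 15 were higher and 3 lower with dopamine. They included further endoplasmic reticulum genes: SDF2L1 (20.1 ± 1.34 and 30.1 ± 3.92 FPKM, corrected log2 fold change 0.75, adjusted p = 0.00469), the chaperone gene HYOU1 (49.8 ± 2.68 and 66.6 ± 0.739 FPKM, 0.45, adjusted p = 0.0169) and DNAJC3, whose product restrains the kinase PERK (3.89 ± 0.677 and 7.79 ± 1.09 FPKM, 0.54, adjusted p = 0.0201). The oxidative stress genes OSGIN1 (5.46 ± 0.698 and 8.70 ± 1.06 FPKM, 0.80, adjusted p = 0.0136) and SLC7A11 (0.76, adjusted p = 0.0237) also passed, as did G0S2, an inhibitor gene of lipid breakdown, at 60.9 ± 5.69 and 91.4 ± 7.18 FPKM (0.67, adjusted p = 0.0444). FST, which encodes the activin-binding protein follistatin, stood at 8.89 ± 0.655 and 7.5 ± 0.641 FPKM (-0.46, adjusted p = 0.0216). Each is limma's adjusted p after the correction, over 3 libraries per group. The count of 28 fell to between 9 and 13 when any 1 of the 6 libraries was left out.

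The cells carried transcripts of both neuroblastoma states. Of the adrenergic genes, HAND2 stood at 128 ± 12.6 FPKM in control cells and 132 ± 9.65 FPKM with dopamine and PHOX2A at 82.7 ± 2.20 and 69.5 ± 4.21 FPKM, while of the mesenchymal genes VIM stood at 903 ± 56.5 and 845 ± 22.3 FPKM and FN1 at 190 ± 8.44 and 184 ± 6.48 FPKM. No member of either list passed (limma, 23 and 29 measured, 6 and 4 with an unadjusted p under 0.05, camera adjusted p = 0.936 and 0.87). FOSL1, a transcription factor gene of the mesenchymal list, stood at 116 ± 18.1 and 78.1 ± 6.11 FPKM and fell when adjusted over that list alone. The noradrenaline transporter gene SLC6A2 stood at 7.70 ± 1.09 and 7.56 ± 0.854 FPKM, whereas DRD1 (0.00703 and 0 FPKM) and the vesicular transporter gene SLC18A2 (0.00723 and 0.0156 FPKM) lay near the floor. FTH1, a ferritin gene, was among the most abundant of the NRF2 and iron members at 1807 ± 75.5 and 2261 ± 55.6 FPKM (adjusted p = 0.11). The lists for immediate early genes, hypoxia, NF-kB, interferon, cholesterol synthesis, ribosome biogenesis, ribosomal proteins, the respiratory chain, other histones and the neuronal synapse did not pass camera either (adjusted p between 0.12 and 0.87).

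Between dopamine and control 12 genes passed, against at most 0 in the other 9 of the 10 splits of the 6 samples, and 5 against at most 0 at 2-fold or more, so 1 of 10 splits gave as many in either case, and 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 3829 genes and the others 53 to 1657. For lists the real split gave 4 and the highest other split 11, with 7 of 10 splits giving as many (4 and 10 after the correction). Lists of genes thus moved together along other splits too. Each other split still set 2 libraries of 1 group and 1 of the other against the reverse. Part of a dopamine effect therefore stays in these splits and adds to the spread within their groups. Structure among the libraries is not told apart from that. The unfolded protein response list had its smallest camera p in the real split (5.72e-14, and 8.11e-06 in the next). For the NRF2 list 1 other split gave a smaller p than the real one (7.23e-07 against 4.43e-06), but none did after the correction (real 8.22e-12, next 7.85e-07). For the G2/M list 4 of 10 splits, the real one included, gave a p as small.

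The rise of the unfolded protein response and NRF2 lists could come from the GC and length trend that differed between the groups. Of their 8 called members 7 stayed past the threshold after the correction, which argues against that trend as the whole cause of these single calls, while XBP1 lost its call with a smaller fold. The unfolded protein response list as a whole went from a median of 0.55 to 0.34, with all 22 members higher before and after, and stayed past the threshold (camera adjusted p = 1.37e-12 and 3.21e-23, or 0.152 and 0.021 with an estimated correlation), so the trend may account for part of its rise and not for all of it. The same holds for the NRF2 list, which went from 0.32 to 0.17 with 21 of 26 members higher before and 24 after (adjusted p = 5.32e-05 and 9.86e-11), its mean over members still higher in each dopamine library than in any control, although with an estimated correlation it passed neither before nor after (0.152 and 0.23). HMOX1 was not the only member of the NRF2 list to rise, since GCLM and TXNRD1 passed by themselves, in 18 and 14 of the 22 alternative settings. Without HMOX1, 20 of 25 members were higher, against 60% of all genes. After the correction 23 were, against 48.7% of all genes. Whether the list without HMOX1 passed camera depended on the correlation used. The list without HMOX1 had a camera adjusted p of 0.000677 with the preset correlation and 0.19 with an estimated correlation. Its median was 0.32, which leaving out 1 of 26 members can hardly move. After the GC and length correction the list without HMOX1 had a median of 0.15 (camera adjusted p = 8.36e-09, or 0.311 with an estimated correlation).

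Leaving out control replicate 1 raised the calls from 12 to 2177. The GC and length correction took that count to 13, and median-of-ratios scaling alone took it to 26. Both a GC and length trend and the scaling by library totals are therefore consistent with it. The library left out had the smallest GC slope of the controls (0.02), but leaving out dopamine replicate 1, which had the slope nearest 0 of its group (-0.03), gave 6 calls, so the position along the trend does not by itself tell which library raises the count. The median-of-ratios size factor of control replicate 1 was 1.014, against 0.944 and 0.967 in control replicates 2 and 3. It was 1.022, 1.027 and 1.067 in dopamine replicates 1, 2 and 3. Leaving out control replicate 1 thus set the groups further apart in scale, but scaling and the GC trend are not told apart by this. A biological origin of the trend was not tested.

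Several genes of the actin cytoskeleton and adhesion had lower means with dopamine without passing, such as PXN at 76.6 ± 6.03 and 56.3 ± 1.63 FPKM and TGFB1I1 at 16.8 ± 0.853 and 12.1 ± 0.881 FPKM (adjusted p = 0.11 for both). A list of 30 other targets of MRTF/SRF and YAP moved toward lower values (limma's camera, unadjusted p = 0.0049, and 0.0493 with an estimated correlation). The median log2 fold change of this list was -0.04. After the GC and length correction the list had a median of -0.12 (limma's camera, unadjusted p = 0.000128). In another split of the 6 libraries the smallest camera p of this list was 0.00733 before the correction, near that of the real split, and 0.00876 after it. These p-values and those of its 2 parts were not adjusted over the 24 lists. They are therefore not comparable with the adjusted p-values of those lists, and no pass is claimed from them. No single gene of the list passed limma's threshold, while 12 were lower and 3 higher at an unadjusted p under 0.05. Of those 12, 10 were among the actin and MRTF/SRF targets. Of the 19 actin and MRTF/SRF targets 14 were lower, with a median of -0.21 (p = 0.000295, and 0.053 with an estimated correlation), and 16 after the correction, with a median of -0.15 (p = 1.26e-05 and 0.051), where the smallest p in another split was 0.00143 before and 0.00338 after it and 10 splits are too few for a share under 0.05. Of the 11 YAP targets 6 were higher, among them F3 (0.75) and ARHGAP29 (0.39), with a median of 0.12 (p = 0.919, and 0.946 with an estimated correlation), and 4 after the correction, with a median of -0.05 (p = 0.368 and 0.519), so a fall of YAP targets by themselves stays open, and no test compared the 2 parts. A lower expression of actin and MRTF/SRF targets may accompany dopamine, but these are genes of the same kind as those that led to the idea, so MRTF/SRF is not told apart from another cause of the fall.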
